A study of Homo sapiens with 6 samples.

How the data were processed

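RNA was measured by bulk RNA-seq in 6 libraries of UMUC3 cells grown for 14 days in the bladders of nude mice, 3 from control cells and 3 from cells with GANAB knockdown. Per the labels' protocols, total RNA was extracted with TRIzol and 200 ng entered library preparation with a VAHTS Universal V6 kit for Illumina. Per the submitters' processing notes, fastp, Salmon, DESeq2 and the build GRCh38 were used; their versions, roles and order, the transcript index and any separation of mouse from human reads are not given in the sources used here. Salmon assigns reads to transcripts by a statistical model, so reads shared by near-identical genes are split by estimate, and reads of the mouse host that match human transcripts could be counted as human.

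The authors deposited a table of estimated counts per Ensembl gene, written as whole numbers and not normalized, and a table of TPM values (expression scaled for gene length and library total), with the same sum in each library. The estimated counts were whole as deposited, so rounding changed none of them. Counts were listed for 21503 genes and TPM for 60233. Every gene of the count table has a total of at least 15 counts and counts in at least 3 libraries. In the tables the knockdown columns carry an abbreviation for knockout, while the labels say knockdown; columns were matched to samples by group and number. Symbols came from the deposited tables, where 4253 genes of the count table had none, and 760 of these were named from a table of Ensembl identifiers. Of the 21503 identifiers, 20986 were found in GENCODE release 29 (GRCh38), which gave coordinates, gene types, lengths and overlaps; the annotation release used by the authors is not given in the sources used here.

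Before the data were examined, the groups, the tests, the rule for named genes, 31 gene lists and most alternatives were fixed. The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the estimated counts of all 6 libraries, with filterByExpr, TMM normalization and Benjamini-Hochberg adjustment at 0.05. It was 2-sided and had no covariate. The filter removed 2073 genes and left 19430. Standard errors were obtained from the log2 fold change and the F statistic. CPM values were computed with TMM library sizes, over a range of 11737837 to 40039584 counts per library. A single count thus weighed least in knockdown library 3 and most in control library 3. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 31 lists; a list needed at least 3 tested members.

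The lists covered glycosylation and protein folding (glucose trimming and calnexin cycle, oligosaccharyltransferase and lipid-linked oligosaccharides, Golgi N-glycan processing, unfolded protein response chaperones, integrated stress response), cell division, DNA replication, interferon, MHC class I, immune ligands, inflammatory cytokines, mesenchymal and epithelial genes, receptor tyrosine kinases, integrins, hypoxia, glycolysis, cholesterol, oxidative phosphorylation, ribosomal proteins, p53 and TGF-beta targets, autophagy, immediate early genes and 7 sets of host cell markers. GANAB was in none of them. Named genes began with GANAB. They included the 12 protein-coding genes with the largest rise and the 12 with the largest fall in log2 fold change among those with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the 3 control and 3 knockdown values. Of each list, up to 3 members with the smallest p, with the most abundant member of each host list, were named. A few further list members that passed, SLC2A3, TM7SF2, SMAD7, MMP14 and COL6A3, were named after their values were seen.

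The test was checked on simulated counts for 19430 genes of 3 control and 3 knockdown libraries with 200 changed genes and a separate list of lowered genes. Each simulated library was drawn independently, so the check does not cover a group whose libraries share a tumour or RNA pool. With 1 pooled spread, 17% of 2-fold and 65% of 4-fold changes were recovered and 7 of 19205 unchanged genes were called; with the spread of each group, 15% and 70% were recovered and 8 were called. Pairs of libraries within a group were compared by chi-square: the statistic per degree of freedom was 63.7 to 158 for control pairs and 6.00 to 7.26 for knockdown pairs, so differences exceeded sampling noise in every pair. Repeat libraries of the same RNA would exceed it too, so this says nothing on whether libraries came from separate animals. Each library was treated as a replicate because the labels number it as a sample of its own.

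Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, the DESeq2 1.42.0 Wald test, limma-voom with and without sample quality weights, no filter or at least 5 CPM in 3 libraries, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) of genes with a mean of at least 1 TPM, the same with 1 added and no filter, leaving out each library in turn, a replicate block, leaving out mitochondrial and ribosomal protein genes or host marker genes, a covariate of host markers (the mean log2 CPM of 65 genes), and stricter thresholds. For lists an estimated correlation, fry and ranks were also tried. Summing the knockdown libraries and thinning each library to 11737837 counts were added after seeing the data. Genes in the TPM table alone (38730) entered no test of counts.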

Results

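UMUC3, an established human bladder carcinoma cell line, was grown for 14 days in the bladders of nude mice, either as control cells or with knockdown of GANAB. GANAB encodes the catalytic alpha subunit of glucosidase II, the enzyme of the endoplasmic reticulum that removes the inner glucose residues of newly attached N-glycans. Bulk RNA-seq gave 3 control libraries and 3 GANAB knockdown libraries. Control libraries 1, 2 and 3 held 36381218, 17942832 and 11737837 estimated counts. Knockdown libraries 1, 2 and 3 held 37659163, 36619291 and 40039584. Because the labels do not say whether the libraries of a group came from separate animals, p-values measured only the spread between these samples, which may be technical. Values below are TMM-normalized CPM, counts scaled to a common library size, as mean ± SD of 3 libraries, and fold changes compare knockdown with control unless another order is given.

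The targeted gene was checked first. GANAB (ENSG00000089597, chromosome 11, 62624826 to 62646726, minus strand, GRCh38) overlaps no other gene in the annotation used, and its values were gene totals over all exons. GANAB stood at 685, 825 and 661 CPM in control libraries 1, 2 and 3 and at 231, 238 and 231 CPM in knockdown libraries 1, 2 and 3. GANAB fell by 1.63 on the log2 scale (SE 0.141, edgeR adjusted p = 0.00239), so the knockdown level was 32.2% of control in the fit. On the deposited TPM scale, GANAB was 234 ± 63.9 TPM in control and 95.03 ± 4.47 TPM in knockdown libraries, 40.7% of control.

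**Figure D1:**
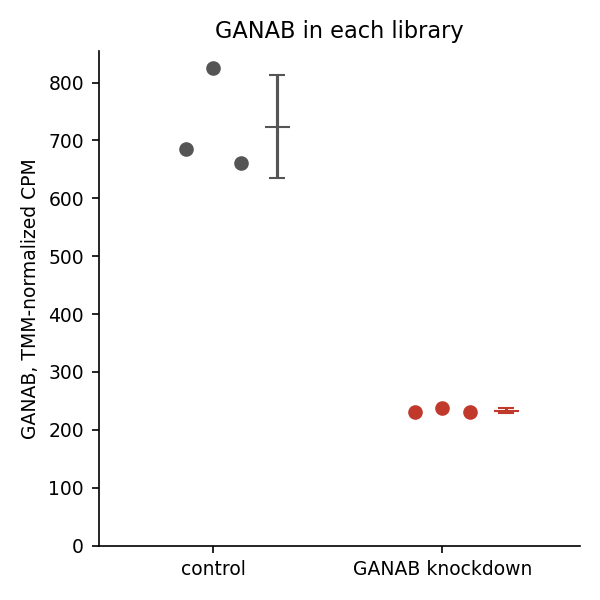
GANAB in each library, in TMM-normalized CPM on an axis that starts at 0; points are single libraries, and the bar beside each group is the mean with its SD over 3 libraries. The 3 knockdown libraries lie at 231 to 238 CPM, below all control libraries at 661 to 825 CPM.

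The comparison of knockdown with control asked how the transcriptome of the tumour cells differed after 14 days in the bladder when GANAB was low. Most tested genes of mitosis and DNA replication fell in the knockdown libraries, and some of cholesterol synthesis, glycolysis and hypoxia fell. Of the type I interferon response 11 of 25 genes rose, and so did some immediate early genes and some genes listed as fibroblast and matrix markers. Of 31 gene lists 16 were called with the preset correlation of camera and 0 with an estimated correlation. Of 19430 genes tested, 1614 changed (edgeR adjusted p under 0.05), with 892 higher and 722 lower in the knockdown. Of these, 629 were higher and 376 lower by at least 2-fold, and 1415 of the 1614 genes were protein coding. The values of control and knockdown libraries did not overlap for 7303 genes, 37.6% of those tested, and 1613 of the 1614 changed genes were among them. By chance 10% would not overlap for 3 against 3, but only if the 6 libraries were independent and of like spread. The knockdown libraries lay much closer together than the controls, so 37.6% cannot be read as an excess over chance. The biological coefficient of variation was 10.7% in the knockdown libraries against 53.4% in the controls. The count of 1614 depended on which libraries entered the fit. Without knockdown library 1, 2 or 3 the count was 62, 115 or 88, and without control library 2 it was 5604. With the knockdown libraries summed to 1 library, a setting chosen after seeing the data, 1 gene passed, MATN2, but a group of a single library loses calls whatever the origin of the libraries. With a score of host marker genes as a covariate 8 genes passed, by DESeq2 3676 and by limma-voom with quality weights 3716. On the TPM scale 828 passed, of which 90.7% were higher against 55.3% in the count fit.

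The genes that rose most included matrix and secreted proteins. MATN2, which encodes the matrix protein matrilin-2, rose 24.8-fold from 9.82 ± 2.36 to 243 ± 8.53 CPM (edgeR adjusted p = 0.000777). SSC5D, a secreted scavenger receptor family member, rose 28.6-fold from 2.23 ± 1.34 to 63.8 ± 0.541 CPM (edgeR adjusted p = 0.00356). IGFBP5, an insulin-like growth factor binding protein, rose 28.3-fold from 0.441 ± 0.482 to 14.3 ± 1.13 CPM (63.6-fold without control library 1). Immune genes among them were C5AR1, the receptor for complement fragment C5a (17.9-fold), the interferon-induced tetherin gene BST2 (12.6-fold) and the chemokine gene CCL5, which rose 12.5-fold from 11.7 ± 5.45 to 148 ± 6.18 CPM. GPNMB, which encodes a transmembrane glycoprotein, rose 15.6-fold, the gap junction gene GJD3 13.3-fold and CSMD3 11.98-fold. MYH11, the smooth muscle myosin heavy chain gene, rose 15.8-fold from 3.39 ± 3.16 to 56.4 ± 1.66 CPM (32.7-fold without control library 1). The cancer-testis antigen gene SPANXB1 rose 23.0-fold to 48.0 ± 2.59 CPM, but it belongs to a family of near-identical copies on chromosome X, so its share of the reads is uncertain. ENSG00000254692, a protein-coding gene model without a symbol on chromosome 14 that overlaps TM9SF1, TSSK4 and CHMP4A, rose from 0.356 ± 0.616 to 15.0 ± 13.2 CPM (edgeR adjusted p = 0.0481), a value that the overlapping genes make uncertain. Its log2 fold change was 5.13 with all libraries, 11.84 and 4.48 without control library 1 and 2, and 4.25 without knockdown library 1. It did not pass without control library 3 or without any of the knockdown libraries (edgeR adjusted p = 0.0829 to 0.225 in these 4 fits). Of the other genes of large rise, IGFBP5, MATN2 (with RPL30), MYH11 (with NDE1, and another gene on its own strand), GJD3, CCL5 and CSMD3 overlap genes of the opposite strand. Because the strand of counting is not given in the sources used here, their values carry the same limit.

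SYT16, a synaptotagmin gene, had the largest fall of the named genes and was 77.6-fold lower in the knockdown (10.5 ± 7.62 to 0.132 ± 0.0775 CPM, edgeR adjusted p = 0.0135). The acute phase gene SAA1 was 67.8-fold lower (20.3 ± 19.9 to 0.296 ± 0.0527 CPM; 30.2-fold without control library 2) and SERPINA3, of the same response, 26.1-fold lower (15.5 ± 11.2 to 0.593 ± 0.260 CPM). The gap junction gene GJB2 was 64.3-fold lower (19.6 ± 14.9 to 0.297 ± 0.232 CPM) and 116-fold lower without knockdown library 3. CDH2, the N-cadherin gene, was 30.0-fold lower (44.5 ± 39.7 to 1.47 ± 0.312 CPM, edgeR adjusted p = 0.0327), and its control libraries 1, 2 and 3 held 48.7, 2.79 and 81.9 CPM. CDH2 did not pass without control library 1, without control library 3 (18.03-fold lower) or without any of the knockdown libraries (edgeR adjusted p = 0.0614 to 0.169 in these 5 fits). TENM2, which encodes a teneurin adhesion protein, was 35.9-fold lower (25.2 ± 17.5 to 0.698 ± 0.419 CPM). GRIK2, a glutamate receptor gene, was 35.7-fold lower (19.1 ± 17.7 to 0.527 ± 0.241 CPM; 18.3-fold without control library 3). The carbonic anhydrase gene CA9, a hypoxia marker, was 30.3-fold lower (16.3 ± 14.0 to 0.536 ± 0.347 CPM; 15.4-fold without control library 2). CES1, a liver-type carboxylesterase gene, was 26.8-fold lower (15.3 ± 17.2 to 0.572 ± 0.264 CPM; 9.72-fold without control library 2). MME, which encodes the peptidase neprilysin, was 23.5-fold lower (258 ± 152 to 10.99 ± 0.364 CPM). ANGPTL4, an inhibitor of lipoprotein lipase, was 21.7-fold lower (404 ± 456 to 18.6 ± 1.29 CPM; 7.72-fold without control library 2). IGFBP3 was 21.4-fold lower (68.5 ± 61.5 to 3.20 ± 1.505 CPM; 11.2-fold without control library 2). Of these 12 genes, 9 overlap other annotated genes, among them CA9 (with ARHGEF39), MME and ANGPTL4 (with antisense transcripts), and GJB2, CES1 and IGFBP3 do not. Of the 24 genes of largest change, 9 passed in each of the 6 fits that left out a library, all of them higher in the knockdown: MATN2, SSC5D, SPANXB1, C5AR1, GPNMB, GJD3, BST2, CCL5 and CSMD3. The other 15 failed to pass when knockdown library 1, 2 or 3 was left out, each in all 3 of these fits. Of the 88 genes of the naming rule besides GANAB that passed with all libraries, 19 passed in each of these fits.

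**Figure D2:**
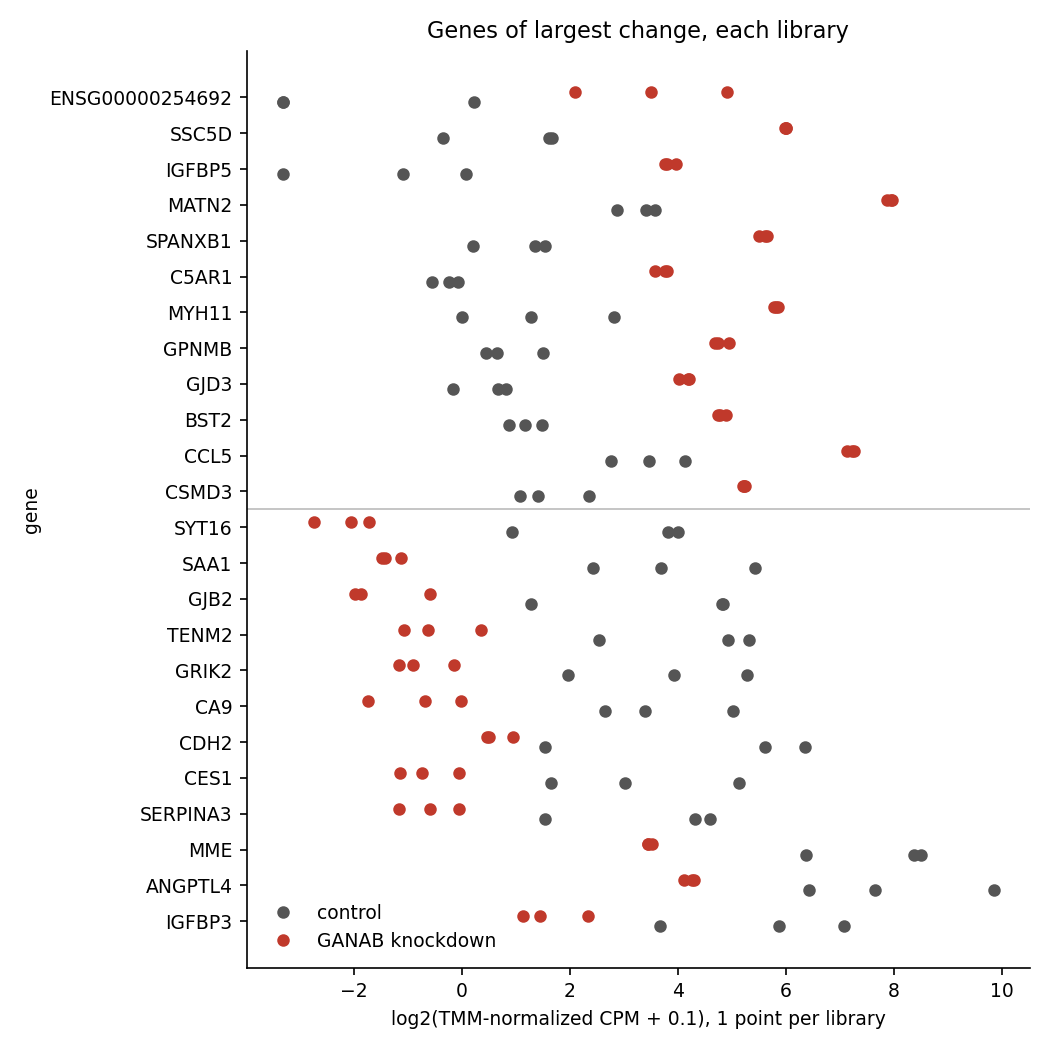
The 12 genes with the largest rise (top) and the 12 with the largest fall (bottom), on a log2 scale of TMM-normalized CPM with 0.1 added; each point is a library, with knockdown in red above control in grey for each gene. The knockdown libraries of most genes lie on top of each other, while control libraries of ANGPTL4 spread from 85.7 to 927 CPM.

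Cell division genes were lower in the knockdown as a group. In the list of G2/M and mitosis genes, 23 of 25 fell and none rose (25 fell adjusted over the list alone), with a median log2 fold change of -1.22 (camera adjusted p = 1.61e-29, adjusted p = 0.244 with an estimated correlation). The mitotic checkpoint kinase gene TTK fell from 54.4 ± 5.42 to 19.4 ± 0.468 CPM (2.80-fold, edgeR adjusted p = 0.00318). CDC20, an activator of the anaphase-promoting complex, fell from 196 ± 9.54 to 82.4 ± 1.63 CPM, and the checkpoint kinase gene BUB1 from 85.5 ± 7.44 to 36.5 ± 3.03 CPM. DNA replication genes fell in 18 of 25 cases (22 adjusted over the list alone) with a median of -1.08 (camera adjusted p = 1.23e-20, adjusted p = 0.244 with an estimated correlation). The replicative helicase subunit genes MCM6, MCM5 and MCM7 fell 2.02-fold, 2.16-fold and 2.18-fold, with MCM6 at 95.1 ± 1.13 CPM in control and 47.1 ± 1.17 CPM in knockdown libraries (edgeR adjusted p = 0.00546). Among 22 targets of p53, CDKN1A, the gene of a cyclin-dependent kinase inhibitor, fell 2.05-fold and TP53I3 rose 1.79-fold (5 rose and 1 fell adjusted over the list alone), and the list was not called (camera adjusted p = 0.485), though it was with fry of limma (adjusted p = 0.0424).

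Metabolic genes fell in part. Of 23 cholesterol biosynthesis genes, 10 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -1.43 (camera adjusted p = 1.32e-19, adjusted p = 0.213 with an estimated correlation). FDPS, which encodes farnesyl diphosphate synthase, fell 2.80-fold from 147 ± 17.9 to 52.7 ± 2.59 CPM (edgeR adjusted p = 0.00318). The sterol reductase gene DHCR7 fell 2.66-fold, while the sterol reductase gene TM7SF2 was the 1 that rose, by 1.20 on the log2 scale. Glycolysis genes fell in 4 of 18 cases (10 adjusted over the list alone; median -0.89, camera adjusted p = 8.77e-07, adjusted p = 0.366 with an estimated correlation). The hexokinase gene HK2 fell 2.18-fold, the lactate dehydrogenase gene LDHA 6.47-fold from 1485 ± 991 to 229 ± 14.6 CPM (edgeR adjusted p = 0.0158; 4.01-fold without control library 2), and the enolase gene ENO1 2.58-fold. The glycolysis call was lost with the host marker score as a covariate (median -0.33, camera adjusted p = 0.0580) and with the test fry of limma (adjusted p = 0.101), and without control library 2 the median was -0.54; adjusted p was 1.82e-09 to 0.366 over all alternatives. Of 24 hypoxia targets, 7 fell and 1, the glucose transporter gene SLC2A3, rose (11 and 2 adjusted over the list alone; median -0.71, camera adjusted p = 1.21e-05, adjusted p = 0.331 with an estimated correlation). Besides CA9 they included STC1, which fell 3.19-fold, and the adenylate kinase gene AK4, which fell 2.03-fold. The hypoxia call was lost with fry of limma (adjusted p = 0.0682; 1.20e-08 to 0.331 over all alternatives), and without control library 2 the median was -0.44. Nuclear genes of oxidative phosphorylation fell in 3 of 26 cases (3 adjusted over the list alone; median -0.37, camera adjusted p = 0.000189, adjusted p = 0.556 with an estimated correlation): ATP5F1A 2.03-fold, NDUFS3 1.66-fold and NDUFA9 1.49-fold. That call was lost without control library 2, where the median was -0.07 (camera adjusted p = 0.0584; 7.87e-07 to 0.815 over all alternatives).

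Genes of the pathway GANAB acts in were tested as a list of their own. Of 18 genes of glucose trimming and the calnexin cycle, a list without GANAB, 3 fell and none rose (4 fell adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.0121, adjusted p = 0.244 with an estimated correlation). CALR, the gene of the lectin chaperone calreticulin, fell 2.87-fold from 1554 ± 403 to 542 ± 6.65 CPM (edgeR adjusted p = 0.00842). PRKCSH, which encodes the beta subunit of glucosidase II, fell 1.75-fold from 399 ± 60.1 to 228 ± 7.76 CPM (edgeR adjusted p = 0.0218), and the cargo receptor gene LMAN1 fell 1.67-fold. Without control library 2 the median was -0.11, and with the host marker score as a covariate the call was lost (camera adjusted p = 0.134). On the TPM scale the median of this list was 0.10 and the call was lost (camera on a limma-trend fit, adjusted p = 0.126 to 0.218 over 3 TPM settings and 0.00390 to 0.244 over all alternatives). The median of all genes was also shifted there, to 0.23 with 1 added to the TPM and low genes left out, against 0.03 in the count fit. Of 24 chaperone genes of the unfolded protein response, 5 fell and none rose (7 fell and 1 rose adjusted over the list alone; median -0.37, camera adjusted p = 0.00232, adjusted p = 0.244 with an estimated correlation). PDIA4 fell 1.71-fold (383 ± 21.9 to 223 ± 6.51 CPM, edgeR adjusted p = 0.0142), HYOU1 1.55-fold and HSP90B1 1.66-fold.

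Other glycosylation and stress groups were not called. In the oligosaccharyltransferase and lipid-linked oligosaccharide list, RPN1, a subunit of the transferase, fell 1.69-fold and was the 1 gene of 30 to pass (1 adjusted over the list alone; camera adjusted p = 0.114), while DPM1 (log2 fold change -0.54) and ALG13 (0.63) did not pass. Without control library 1 or 3 this list was called downwards (camera adjusted p = 0.0276 and 0.0254; 0.0254 to 0.866 over all alternatives). Of 23 Golgi N-glycan processing genes, the galactosyltransferase gene B4GALT2 fell 1.75-fold, MGAT4A fell 3.27-fold and the mannosidase gene MAN1C1 rose 3.24-fold (3 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0931). Golgi genes were called downwards without control library 2 (camera adjusted p = 0.00111; 0.00111 to 0.366 over all alternatives). Of 25 integrated stress response genes, ATF5 rose 2.02-fold and PPP1R15A, which encodes a phosphatase subunit acting on eIF2 alpha, rose 5.64-fold from 225 ± 134 to 1270.4 ± 20.02 CPM (edgeR adjusted p = 0.0280; 2 rose and 1 fell adjusted over the list alone). PSPH had a log2 fold change of -0.81 without passing, and the list, with a median of -0.08 and a mean of 0.14, was not called (camera adjusted p = 0.972). Autophagy and lysosome genes (camera adjusted p = 0.285) held NPC1, which fell 2.19-fold, and ULK1, which rose 1.54-fold, among 26 genes (1 rose and 1 fell adjusted over the list alone), with GAA at 0.42. No gene of 30 cytosolic ribosomal protein genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.624), with log2 fold changes of -0.34 for RPL5 and 0.29 for RPS9.

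Interferon and antigen presentation genes were higher in part. Of 25 type I interferon response genes, 11 rose and none fell (18 rose adjusted over the list alone), with a median of 1.14 (camera adjusted p = 2.03e-16, adjusted p = 0.244 with an estimated correlation). BST2 rose from 2.18 ± 0.478 to 27.8 ± 1.597 CPM (edgeR adjusted p = 0.000981), IFIT2 rose 6.81-fold from 23.8 ± 7.53 to 162 ± 4.63 CPM, and the ubiquitin-like modifier gene ISG15 rose 2.98-fold from 56.9 ± 9.29 to 169 ± 5.47 CPM. Of 20 genes of MHC class I and antigen processing, 5 rose and 1, CALR, fell (7 and 1 adjusted over the list alone; median 0.31, camera adjusted p = 0.0263, adjusted p = 0.549 with an estimated correlation). HLA-F rose 2.28-fold from 19.5 ± 1.61 to 44.4 ± 2.71 CPM and HLA-B 1.86-fold from 554 ± 104 to 1028 ± 9.50 CPM, with the limit that class I genes share sequence and the split of their reads is uncertain. Without control library 1 this list was no longer called (camera adjusted p = 0.225; 0.000291 to 0.549 over all alternatives).

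Other immune genes moved in both directions. Of 21 inflammatory cytokine and NF-kappaB target genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone; median 0.54, camera adjusted p = 0.00409, adjusted p = 0.556 with an estimated correlation). Besides CCL5, the neutrophil chemokine gene CXCL1 rose 5.54-fold, whereas the monocyte chemokine gene CCL2 fell 2.70-fold from 33.8 ± 10.6 to 12.5 ± 0.481 CPM (edgeR adjusted p = 0.0161). Without control library 2 the median was 0.28 and the list was not called (camera adjusted p = 0.0711; 4.58e-05 to 0.652 over all alternatives). Of 25 immune ligand and checkpoint genes, 3 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.824, but 0.0343 with fry of limma). The galectin-9 gene LGALS9 rose 11.7-fold from 1.93 ± 1.19 to 22.1 ± 1.77 CPM, and the complement inhibitor gene CD59 and the surface glycoprotein gene CD24 fell 1.57-fold and 1.95-fold.

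Matrix and mesenchymal genes were higher in part. The mesenchymal list had 6 rising and 2 falling members of 25 (9 and 5 adjusted over the list alone; median 0.67, camera adjusted p = 0.0153, adjusted p = 0.331 with an estimated correlation). SPARC, a collagen-binding matrix protein gene, rose 4.61-fold from 179.8 ± 28.4 to 829 ± 25.5 CPM (edgeR adjusted p = 0.00132). The transcriptional repressor gene SNAI1 rose 3.21-fold and the tenascin-C gene TNC 1.77-fold, while CDH2 and the membrane protease gene MMP14 fell. The call was lost without control library 2 (median 0.30, camera adjusted p = 0.290) and with host marker genes left out (median 0.16, camera adjusted p = 0.324; 0.000604 to 0.584 over all alternatives). Leaving out host marker genes also took rising members such as SPARC and TAGLN out of this list, so that loss is not a test of host RNA. Of 21 epithelial and urothelial genes, the uroplakin gene UPK1A rose 7.89-fold from 0.483 ± 0.297 to 3.76 ± 0.639 CPM and the transcription factor gene FOXA1 2.33-fold (4 rose and none fell adjusted over the list alone), and GATA3 had a log2 fold change of 1.81 without passing. This list had a median of 1.11 (camera adjusted p = 0.00409, adjusted p = 0.244 with an estimated correlation), and with at least 5 CPM required in 3 libraries only 5 members were left, with a median of 0.37, and the call was lost (camera adjusted p = 0.423; 0.00101 to 0.423 over all alternatives). Of 20 TGF-beta and SMAD targets, ID2 rose 3.65-fold, TSC22D1 2.34-fold and SMAD7 by 1.29 on the log2 scale, and LTBP2 fell 1.71-fold (5 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0692). That list was called upwards without control library 1 or 2 or any 1 of the knockdown libraries (camera adjusted p = 0.00129 to 0.0455; 0.00129 to 0.568 over all alternatives).

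Surface receptors and immediate early genes completed the lists. FGFR2, PDGFRB and LRP1 rose 3.70-fold, 2.35-fold and 1.91-fold among 26 receptor tyrosine kinases and glycoprotein receptors (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.149). Among 26 integrin and adhesion genes 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.722): the adhesion molecule gene L1CAM rose 3.37-fold from 33.8 ± 5.39 to 114 ± 1.72 CPM, and ITGB5 and ALCAM fell 1.92-fold and 2.37-fold. Of 23 immediate early genes, which respond to growth factors, stress and tissue handling, 4 rose and none fell (9 rose adjusted over the list alone; median 1.08, camera adjusted p = 5.15e-09, adjusted p = 0.366 with an estimated correlation). KLF4 rose 4.96-fold from 34.2 ± 4.68 to 169 ± 0.749 CPM (edgeR adjusted p = 0.000981), the phosphatase gene DUSP1 4.14-fold from 413 ± 47.6 to 1709.7 ± 32.7 CPM and KLF2 7.37-fold. Without control library 1 the median of this list was 1.64.

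**Figure D3:**
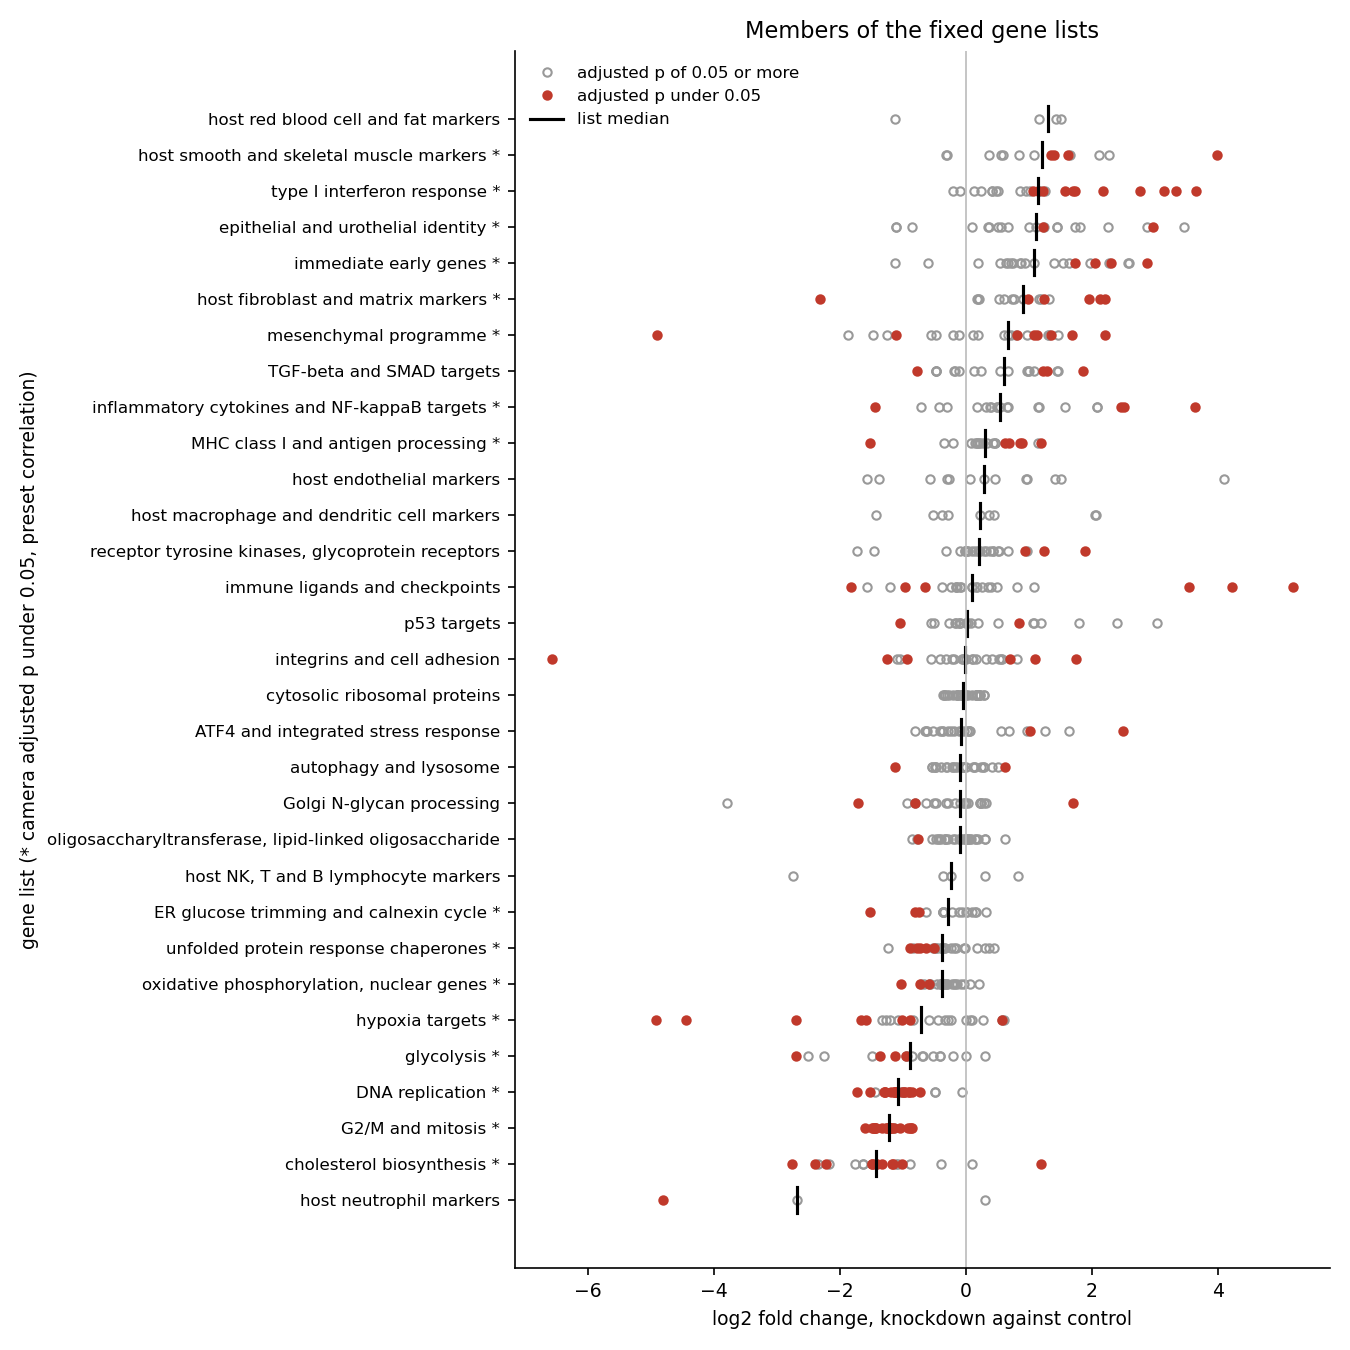
Log2 fold changes of the tested members of the 31 gene lists, ordered by list median (black line); filled points had an edgeR adjusted p under 0.05 over all genes tested, and an asterisk marks the 16 lists called by camera with the preset correlation. The G2/M and mitosis list has 23 filled points around a median of -1.22 and the interferon list 11 around 1.14, and none of the 31 lists was called with an estimated correlation.

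Markers of the cell types a mouse bladder could add were measured in the same libraries. Summed fibroblast and matrix markers were higher in the knockdown, at 1792 ± 42.6 CPM against 628 ± 118 CPM in control, and summed muscle markers were 794 ± 19.1 against 407 ± 158 CPM. These were the libraries in which the mesenchymal, interferon and immediate early lists were higher. With the host marker score as a covariate 8 of the 16 list calls were lost: glucose trimming (median -0.19 with the score), inflammatory (-0.01), mesenchymal (0.09), epithelial (0.89), glycolysis (-0.33), oxidative phosphorylation (0.054), fibroblast (-0.40) and muscle (0.19). The score was built from the genes of the host lists, so the loss of the fibroblast and muscle calls carries no information. The mesenchymal list also shares genes with the score, among them SPARC and TAGLN. With fry of limma 4 were lost, inflammatory, hypoxia, glycolysis and oxidative phosphorylation, and 3 were gained, immune ligands (adjusted p = 0.0343), p53 targets and TGF-beta targets (adjusted p = 0.0424 for both). Of 17 tested fibroblast and matrix markers, 5 rose and 1, COL6A3, fell (6 and 1 adjusted over the list alone; median 0.91, camera adjusted p = 9.60e-06, adjusted p = 0.244 with an estimated correlation). SPARC was the most abundant of them, at 179.8 ± 28.4 CPM in control and 829 ± 25.5 CPM in knockdown libraries, and it is also in the mesenchymal list. The collagen VI genes COL6A1 and COL6A2 rose 3.88-fold and 1.98-fold. Values of human genes do not tell host from tumour RNA, so the sums do not show that host RNA rose. Without control library 1 the median of the fibroblast list was 1.82. Muscle markers rose in 4 of 14 cases (4 adjusted over the list alone; median 1.21, camera adjusted p = 0.000363, adjusted p = 0.366 with an estimated correlation), with TAGLN and ACTA2 up 2.54-fold and 3.07-fold beside MYH11, and MYLK at 116 ± 79.8 and 149 ± 2.05 CPM.

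The remaining host lists were not called. Endothelial markers (13 tested, none past the threshold over all genes or adjusted over the list alone, camera adjusted p = 0.752) summed to 227 ± 157 CPM in control and 168 ± 2.80 CPM in knockdown libraries. The sums were 164, 407 and 112 CPM in control libraries 1, 2 and 3, and only control library 2 lay above the knockdown libraries. Log2 fold changes were 4.11 for CDH5, -1.38 for TIE1, -1.57 for ROBO4 and -0.31 for ENG, the most abundant, and the size of each depended on a single control library. Without control library 1, the only control with CDH5 counts, CDH5 had 9.44, and without control library 2 TIE1 had -0.42, ROBO4 -0.86 and ENG 0.40. Macrophage and dendritic cell markers summed to 173 ± 111 CPM in control and 82.9 ± 1.03 CPM in knockdown libraries. Control library 2 was highest, at 300 CPM against 124 and 94.7 CPM in control libraries 1 and 3. Most of the sum was CD68 at 139 ± 101 and 51.8 ± 0.393 CPM, with CSF1R and CYBB at 0.686 and 2.20 CPM in the knockdown. None of 9 passed, also adjusted over the list alone, and the median of 0.22 and the camera direction, downwards, differed in sign (camera adjusted p = 0.962). Neutrophil markers had 3 tested members, of which FPR1 fell 27.9-fold from 4.89 ± 4.95 to 0.172 ± 0.00679 CPM (12.9-fold without control library 2), ELANE had -2.68 and MMP9, the most abundant, 0.31 (2 fell adjusted over the list alone, camera adjusted p = 0.175, or 0.00907 without control library 3, with 0.00907 to 0.615 over all alternatives). Lymphocyte markers summed to 4.57 ± 0.797 and 4.82 ± 1.17 CPM, with CD3G at -2.74, PTPRC at 0.83 and KLRD1 at 0.31 (none of 5 over all genes and 1 fell adjusted over the list alone, camera adjusted p = 0.624). Red blood cell and fat markers summed to 2.12 ± 0.804 and 3.55 ± 0.520 CPM, with CFD at 1.44 and LPL at 1.51, and none of 4 passed, also adjusted over the list alone (camera adjusted p = 0.485).

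**Figure D4:**
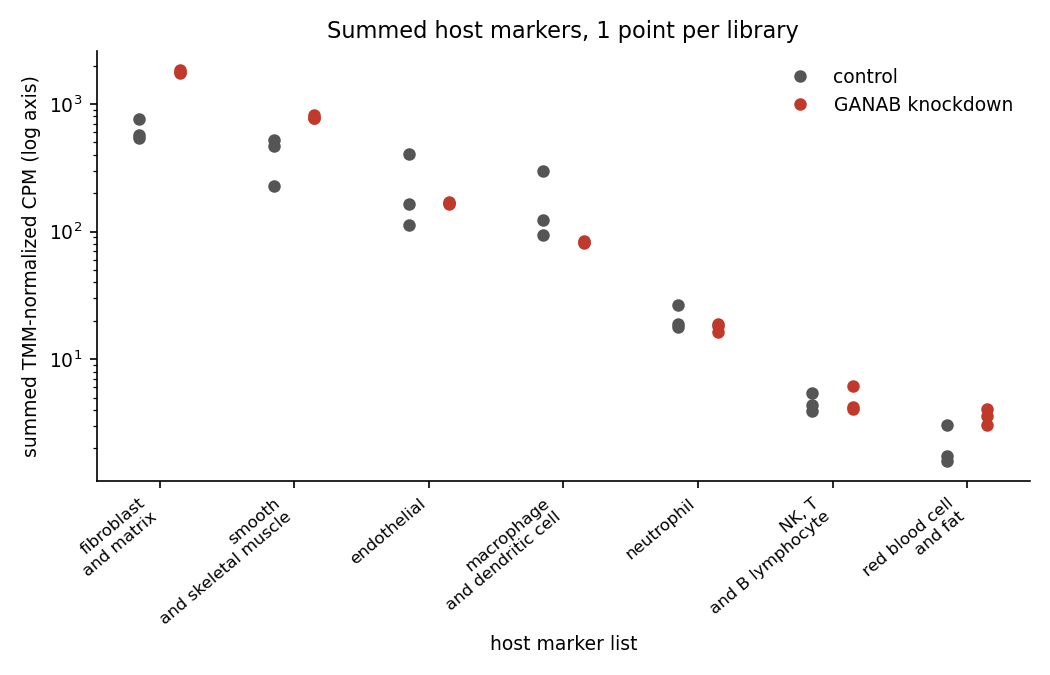
Summed TMM-normalized CPM of the markers of 7 host cell types in each library, on a log axis, with control in grey and knockdown in red. Fibroblast and muscle sums lie higher in all 3 knockdown libraries (1762 to 1841 and 783 to 816 CPM) than in the controls (545 to 763 and 228 to 527 CPM), and macrophage sums lie lower (81.7 to 83.7 against 94.7 to 300.4 CPM).

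Libraries also differed in composition. Mitochondrial ribosomal RNA made up 29.2% of the counts of control library 1, against 1.10% and 0.928% in control libraries 2 and 3 and 2.43%, 2.11% and 2.37% in knockdown libraries 1, 2 and 3. Protein-coding genes held 66.8% of the counts of control library 1, against 94.2% to 96.7% in the other libraries. Small nucleolar RNA held 0.0715% there, against 0.00114% to 0.00818% in the other libraries. Without control library 1 the count of changed genes was 1601, of which 1107 were also among the 1614. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.899 to 0.930 between control libraries and 0.983 to 0.984 between knockdown libraries.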

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

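The test of the spread of the knockdown libraries was chosen only after the count of 1614 changed genes was seen. Of the 10 ways to split 6 libraries into 3 and 3, 1, the real grouping, reached 1614 changed genes and the highest of the others reached 0, but 10 splits are too few for a share under 0.05. With the host marker score as a covariate, 99.9% of the 1614 genes were no longer called, and because the score itself followed the group (R squared 68.7%), the covariate also removes a real difference, so RNA of mouse host cells stays open. The biological coefficient of variation was 10.7% in the knockdown and 53.4% in the control libraries, so knockdown libraries taken from the same tumour or RNA pool also stay open, since the labels give no repeat libraries to compare that spread with.

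For the lower mitosis and DNA replication genes, the tests with the host marker score and with thinned libraries were chosen only after the result was seen, and the test of gene length was set before it. After regression on gene length, GC content and expression over 19028 genes the median of the 50 genes was -1.04 against -1.16 before, and 39 of 41 called members were still called after each library was thinned to the shallowest, and both argue against those explanations. Fibroblast and muscle markers were higher in the knockdown (1792 against 628 CPM and 794 against 407 CPM). With the host marker score as a covariate the median was -0.94. The score was 2.03, 1.16 and 1.15 in control libraries 1, 2 and 3 and 2.28 to 2.36 in the knockdown libraries. It followed the group, and within groups it mainly set control library 1 apart. That fit therefore cannot decide the question, and RNA of mouse host cells stays open. Slower division of the knockdown cells is a hypothesis, and counting dividing cells in separate tumours would test it. Neither list was called with an estimated correlation (camera adjusted p = 0.244).

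For the higher interferon response genes, the tests of leukocyte markers and of the host marker score were chosen only after the result was seen, and the test of gene length was set before it. After regression on length, GC content and expression the median was 1.24 against 1.14 before, which argues against such a bias. Summed leukocyte markers were 105 ± 2.89 CPM in the knockdown and 199 ± 115 CPM in the control libraries, but CD68 carried that difference: without it the sums were 53.7 ± 2.86 and 59.4 ± 14.1 CPM and overlapped, so RNA of mouse leukocytes stays open. Fibroblast and muscle markers were higher in the knockdown, and with the host marker score as a covariate the interferon median was 0.96. Because that score followed the group, the fit cannot decide whether the trend of those markers is the whole cause. Reads aligned to both genomes would tell host from tumour RNA, and the list was not called with an estimated correlation (camera adjusted p = 0.244).

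The search of genes present only in the TPM table was chosen only after that table was seen to be larger. In 43 of 38730 such genes every knockdown value was above every control value with at least 0.5 TPM in each knockdown library, and 26 of them were listed at 0 in all 3 controls. The median of their highest knockdown TPM was 3.05, and 1 was protein coding, GNG8, a G protein gamma subunit gene (0, 0 and 0 TPM in control and 1.40, 0.803 and 2.13 TPM in knockdown libraries). In 5 genes the order was the opposite: C6orf52, SUGCT, VTRNA1-1, SNORD12C and ENSG00000260814. The controls were sequenced less deeply in 2 of 3 libraries, so short or rare transcripts could be missed there, a cause that was not tested.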

How the results depend on the processing

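The count of 1614 changed genes was 3676 by the DESeq2 Wald test, 3716 by limma-voom with quality weights, 828, 526 and 46 by limma-trend on TPM with 1 added, 0.1 added, and 1 added without a filter, 631 with a replicate block, 8 with the host marker score, 1005 at an absolute log2 fold change of at least 1 and 244 at an adjusted p under 0.01; leaving out 1 library gave 62 to 5604, with 62, 115 and 88 without knockdown library 1, 2 and 3 and 5604 without control library 2. With the knockdown libraries summed to 1, added after seeing the data, it was 1. GANAB no longer passed on TPM with 0.1 added (-1.26, limma adjusted p = 0.0553) and with 1 added without a filter (-1.25, limma adjusted p = 0.0877), with the host marker score (-1.51, edgeR adjusted p = 0.115) and with the knockdown libraries summed (-1.62, edgeR adjusted p = 0.744, where a group of a single library widened the error and left the log2 fold change nearly as it was, at -1.63 with all libraries); leaving out 1 library gave -1.75 to -1.52, and adjusted p over all alternatives was 1.44e-21 to 0.744 (DESeq2 to edgeR). Of 31 lists 16 were called, 9 with the host marker score and 0 with an estimated correlation; leaving out 1 library gave 15 to 18. With the host marker score the median of oxidative phosphorylation genes was 0.054 against -0.37 (camera adjusted p = 0.815) and that of cytosolic ribosomal proteins 0.37 against -0.04 (camera adjusted p = 0.00369). Of 2413 values for 113 named genes 1788 were alike, 580 weaker, 45 stronger and 0 reversed, where reversed needs a change of sign and a call in either fit; 14 values of 7 genes that were not called changed sign without a call (MYLK, ENG, CYBB, PTPRC, RPL5, LPL and KLRD1). The numbers of the replicates do not state a pairing; deviations correlated by 0.00223, 0.0171 and 0.0218 between libraries of the same number. The cause was not tested.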

Other observations

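Genes in this section were chosen after their values were seen. The control libraries differed from each other in the genes given next, and no gene list was tested between control libraries. The endoplasmic reticulum chaperone gene HSPA5 stood at 5079, 759 and 4595 CPM in control libraries 1, 2 and 3 and at 2584, 2661 and 2702 CPM in the knockdown libraries, so its log2 fold change of -0.39 averaged over control libraries on both sides of the knockdown. HERPUD1, a gene of the degradation of misfolded proteins, had 36.9 CPM in control library 2 against 259.8 and 303 CPM in the others. LDHA had 1093, 2612 and 750.1 CPM and the stress-responsive gene NDRG1 425, 1047 and 171 CPM, with control library 2 highest. Without control library 2 the count of changed genes was 5604.

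AXIN2, a negative regulator and target of WNT signalling, rose from 7.98, 2.31 and 8.81 CPM in control to 49.5, 50.9 and 47.3 CPM in knockdown libraries (log2 fold change 2.96, edgeR adjusted p = 0.0128). A wider rise of WNT targets might accompany it, and it was tested on 15 other WNT target genes, of which 8 were tested and 0 changed (median 0.17). The camera test of limma gave an adjusted p = 0.569, adjusted over this set and the fatty acid set below, an adjustment added after the p-values were seen. That test leaves the hypothesis open, since the list is short; protein levels of beta-catenin would test it.

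Of 23 cholesterol synthesis genes 10 fell and 1 rose, a list call that was lost with an estimated correlation (camera adjusted p = 0.213). Lower activity of a regulator shared with fatty acid synthesis, such as the SREBP transcription factors, could lie behind lower levels of genes of both pathways. The hypothesis was tested on 15 fatty acid synthesis genes, of which 4 fell and 1 rose (median -0.59, limma camera adjusted p = 1.16e-06, adjusted p = 0.0119 with an estimated correlation). These values were adjusted over this set and the WNT set alone, and the cholesterol value over the 31 lists, so they cannot be compared directly. FASN, which encodes fatty acid synthase, fell by 1.75 on the log2 scale (edgeR adjusted p = 0.00132), the desaturase genes SCD and FADS1 fell by 1.43 and 1.89, and THRSP, with a mean under 1 CPM in both groups, rose. This is in line with the hypothesis, while SREBF1, the gene of a regulator of both pathways, had a log2 fold change of 0.80 and did not pass. Measuring the processed SREBP proteins in separate tumours would test it.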
